A study of Mus musculus with 4 samples.

How the data were processed

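Lung tissue from embryonic and neonatal C57BL/6 mice was extracted with TRIzol and total RNA was sequenced, per the labels' protocols, giving 1 library for each of 4 stages. The deposited files list circRNAs per library. Their column names and the name of the file type match the caller CIRI, and the submitters' processing notes name cutadapt, HISAT2 2.0.5, StringTie, HTSeq, BWA and the build mm10 without saying what each did. Every listed circRNA has 2 or more junction reads, found by reading the files, and what else was removed by filtering is not given in the sources used here. The listed reads of all 4 libraries name the same flow-cell lane, 1 in all, and whether the libraries were prepared together is not given in the sources used here.

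Junction reads were deposited as raw counts of reads that cross the back-splice junction, per the file headers. Non-junction reads were deposited as raw counts of reads aligned linearly across the same ends, and a blank there was read as 0. The junction ratio was deposited as a fraction, junction reads times 2 over junction reads times 2 plus non-junction reads, per the file headers, and was recomputed with 0 mismatches in any library. The deposited alignment-pattern numbers count distinct alignment patterns among the junction reads of a circRNA, per the file headers and what CIRI writes in that column. A circRNA was identified by chromosome, start and end. The plan named the strand as well, but the files hold no strand column.

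Host genes were taken from the deposited Ensembl identifiers, 4647 of 4653 of which are in GENCODE release M21 on the same build. Exon numbers were taken from M21 transcripts with both ends at exon boundaries, or otherwise from a transcript whose exons contain both ends. In that case an end can lie inside an exon, as for the Col4a1 circles of exons 24 to 26, 24 to 27 and 23 to 28. Of the distinct circRNAs 74.7% had both ends at exon boundaries of 1 transcript. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

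Depth was 25983, 31218, 36156 and 28332 listed junction reads in order of stage. Between 37.4% and 41.5% of the circRNAs of a library had 2 reads, so presence in a list depends on depth. For each pair of libraries, a circRNA with 10 or more junction reads in the pair was compared by the ratio of its shares of listed junction reads, with an exact conditional binomial 95% interval. It was called higher or lower when the ratio was at least 2-fold and the interval excluded 1. A circRNA not listed in a library was set to 3 reads, and its fold is written "at least" and called a lower bound. The bound holds for its exact coordinates and only if the library had 3 or fewer reads of it, since further filtering is not known. Reads listed at ends a few bases away are not counted in it. The calls that counting noise gives were counted in 1000 Poisson simulations with equal shares. Junction ratios were compared by the odds ratio of junction to non-junction reads with Woolf's interval and 0.5 added to each count. Shares of gene lists carry exact Clopper-Pearson intervals.

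For gene lists, junction reads were summed per host gene, 0.5 reads were added, and the median log2 ratio of the list was placed among 10000 random lists of the same size matched on abundance. A list stood apart outside the central 95% of random lists. Lists with under 3 measured genes are given as values. The 22 lists were cell cycle, alveolar type 1 epithelium, alveolar type 2 epithelium, ciliated and secretory airway epithelium, lung epithelial progenitors and transcription factors, foetal growth genes, endothelium, lung mesenchyme and fibroblasts, extracellular matrix and elastic fibre, smooth muscle and pericytes, immune cells, erythroid cells, neurons with neural crest and neuroendocrine cells, cardiac and striated muscle, mesothelium, cartilage, Wnt signalling, TGF-beta and BMP signalling, FGF with Hedgehog and Notch signalling, RNA-binding proteins and splicing factors, chromatin regulators, and widely described circRNA hosts. Some genes stand in more than 1 list, for instance Ezh2 in the cell-cycle and chromatin lists.

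The comparisons, tests, thresholds, gene lists, most alternatives and the rule for named circRNAs were fixed before the data were examined. That rule ranks called circRNAs by the end of the interval nearest to 1 and names the leading 12 higher and 12 lower for the alveolar against the pseudoglandular library, and 8 and 8 for each consecutive step. A gene is named once per direction, and circRNAs without a host gene are counted but not named. It also names the 10 circRNAs with most junction reads, the 5 hosts with most distinct circRNAs, 6 higher and 6 lower by junction ratio, and up to 4 members of each list with most junction reads. Not every circRNA that the rule selects is described or drawn. A few further list members, called or not, are named in the report and were chosen after their values were seen.

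Chosen after the data had been seen were the grouping of circRNAs as repeat-end or few-pattern, the restriction to both ends at exon boundaries, merging of junctions with both ends within 5 bases for the comparisons and named circRNAs, non-junction scaling for the lists, hosts from M21 in the lists for circRNAs without a deposited host, and a stricter bound on alignment patterns for the matrix list (0.5 in place of 0.4). Repeat-end means a direct repeat of 6 or more bases at the ends, which could be searched for 11494 of 13499 circRNAs. Few-pattern means 10 or more reads in a library with distinct patterns under 0.4 times the reads, counting at most 50 reads. Because these bounds were set with the Eln and Col4a1 junctions in view, the share of such circRNAs among matrix hosts is partly set by the definition.

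Other settings, fixed with the comparisons and thresholds, were scaling by the median of ratios or, for calls, by non-junction reads, minimums of 20 reads or none, circRNAs listed in both libraries, host-gene sums, the exon type alone, totals without the most abundant circRNA, thinning to 25983 reads, and 2 reads added for lists. Relative to scaling by totals, the median of ratios moved log2 ratios by 0.18 for the alveolar against the terminal sac library and 0.20 for the alveolar against the pseudoglandular. Scaling by non-junction reads moved them by 0.63 for the terminal sac against the canalicular, -0.43 for the alveolar against the terminal sac and 0.29 for the alveolar against the pseudoglandular. Leaving out replicates is not possible with 1 library per stage.

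The routines for shares, odds ratios and lists were tested on simulated data with the real totals, 200 circRNAs of which were changed by known folds. For shares, 3-fold changes were called in 84 of 100 circRNAs for the canalicular against the pseudoglandular library, 86 for the terminal sac against the canalicular, 88 for the alveolar against the terminal sac and 82 for the alveolar against the pseudoglandular, and 8-fold changes in 100 of 100 in each comparison. Unchanged circRNAs were called in 15 of 890, 26 of 1104, 28 of 1031 and 13 of 791, in the same order. For odds ratios, 3-fold changes were called in 79 of 100, 77 of 100, 81 of 100 and 80 of 98, 8-fold changes in 96 of 96, 96 of 96, 94 of 95 and 89 of 90, and unchanged circRNAs in 4 of 218, 9 of 334, 10 of 271 and 7 of 166. For lists of 10 genes, 100 of 100 with a 3-fold shift stood apart in each comparison, and 3, 3, 5 and 4 of 100 unchanged lists did. The unchanged lists were drawn from the same pool as the random lists, so their rate is largely set by the central 95%. Lists of fewer genes, as several reported here, were not simulated.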

Results

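Circular RNAs (circRNAs), which form when a downstream splice site joins an upstream one, were measured by sequencing total RNA from the lungs of C57BL/6 mice. The series holds 4 libraries, 1 for each stage: pseudoglandular (embryonic day 14.5), canalicular (embryonic day 16.5), terminal sac (embryonic day 18.5) and alveolar (newborn day 7.5). The labels do not say how many animals went into a library. With 1 library per stage there is no replicate check and no p-value is given, so each comparison is of libraries, not of conditions. Intervals are 95% intervals that cover counting error of reads only. Because reads amplified by PCR are not independent molecules, these intervals can be too narrow and the calls simulated from counting noise too few. The pseudoglandular library listed 4599 circRNAs with 25983 junction reads, the canalicular 4947 with 31218, the terminal sac 5564 with 36156 and the alveolar 4474 with 28332. Circles of the exon type held 91.3% of junction reads in the pseudoglandular library, 93.6% in the canalicular, 94.0% in the terminal sac and 92.9% in the alveolar.

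The collagen gene Col4a1, which encodes a chain of the basement-membrane collagen type IV, gave the circRNA with most junction reads over the 4 libraries, 1994 for exons 35 to 39 on chromosome 8 (11217265 to 11218967, build mm10). A circle from Tulp4, a member of the tubby-like family, followed with 1836 junction reads. Next came 1646 junction reads for Eln (elastin, the core protein of elastic fibres), all in the alveolar library. Strn3, which encodes a striatin scaffold protein, gave 1253 junction reads from exons 2 to 7, and Sftpc, which encodes surfactant protein C, gave 893. The remaining circles among the 10 most abundant came from Zfp827 (863 junction reads), Ube2k (779), Mettl9 (743), Nfix (677) and Ttc3 (666). Rere, a transcriptional co-regulator, hosted 33 distinct circRNAs, the histone methyltransferase gene Ehmt1 hosted 32, the cytoskeletal linker gene Macf1 31, the cohesin gene Stag1 30 and the chromatin remodeller gene Chd2 28. Of the circles from Col4a1, Eln and Sftpc just named, the one from Eln has a direct repeat of 14 bases at its ends, and the other two have few distinct alignment patterns for their reads.

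Over the 4 libraries 13499 distinct circRNAs were listed. Of these, 10046 were listed in 1 library, 1718 in 2, 838 in 3 and 897 in all 4, and the last group held 50.8% of all junction reads. Among the 1038 circRNAs with 10 or more junction reads in some library, 655 were listed in all 4 and 99 in 1. A direct repeat of 6 or more bases at the ends (repeat-end) or few alignment patterns (few-pattern) marked 326 circRNAs, a grouping defined after the data had been seen. They made up 43.4% of the 99 circRNAs just given and 1.07% of the 655. Their share of junction reads was 3.86% in the pseudoglandular library, 3.90% in the canalicular, 5.69% in the terminal sac and 13.4% in the alveolar.

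The alveolar library was set against the pseudoglandular one to ask which circRNAs differ between the latest and the earliest stage sampled. Hosts that mark alveolar type 2 cells, the surfactant-producing cells of the lung, held 0.0231% of junction reads (interval 0.00847 to 0.0503) in the pseudoglandular library and 2.77% (2.58 to 2.97) in the alveolar. All 5 measured hosts of that list rose, with Sftpc at least 159-fold higher, the lamellar-body gene Lamp3 at least 33.6-fold, Sftpb (surfactant protein B) at least 33.0-fold and the phosphate transporter gene Slc34a2 at least 8.25-fold. The list had 6 pseudoglandular reads in all, so hosts reached the minimum of 10 reads in the pair mainly through the alveolar library. That minimum largely sets the direction of the 5, which is therefore little support. Elastin was at 3 junction reads in the pseudoglandular library and 1665 in the alveolar, a ratio of 509 (174 to 2471), and the matrix list as a whole went from 2.16% to 11.1% of junction reads. Of the 1665 elastin reads, 1646 came from 1 repeat-end circle that the pseudoglandular library does not list. Without repeat-end and few-pattern circRNAs the matrix list went from 0.733% to 1.65% and the type 2 list from 0.0240% to 0.526%. Of 7 endothelial hosts 4 were higher and 1 lower, the higher including Pecam1, an adhesion molecule of endothelial cells, by 11.9-fold (3.79 to 60.3) and Prex2, a Rac exchange factor, by 28.9-fold (7.67 to 244). Of 15 cell-cycle hosts 6 were lower and 9 neither higher nor lower, the lower including Bub1b, a spindle-checkpoint kinase, which was 10.5-fold lower (4.56 to 29.9), and Ezh2, the catalytic subunit of a histone methyltransferase complex, 2.65-fold lower (2.01 to 3.53). In the Wnt list the co-receptor gene Lrp6 was 2.65-fold lower (1.79 to 4.002) and Ctnnb1 (beta-catenin) at least 8.36-fold lower.

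Of 933 circRNAs compared between the alveolar and pseudoglandular libraries, 114 were higher and 162 lower, where counting noise alone gave 8.78 and 11.2 on average. The higher circle ranked at the top was Eln exons 17 to 22 (chromosome 5, 134715684 to 134719222), at least 503-fold higher with 1646 alveolar junction reads. Sftpc followed at least 159-fold higher (521 reads), then Col1a2, a chain of the fibrillar collagen type I, at least 37.9-fold (124 reads) and Sftpb at least 33.0-fold (108 reads). A Col4a1 circle of exons 24 to 26 was at least 26.6-fold higher (87 reads), and Lamp3 exons 2 to 5 (chromosome 16, 19673391 to 19701382) at least 25.4-fold (83 reads). Fbn1 (fibrillin-1 of microfibrils) was at least 17.4-fold higher, Col5a1 15.3-fold, Crip2 14.98-fold, Hmcn1 (hemicentin-1) 11.6-fold and Col3a1 11.6-fold, each as a lower bound. Rmdn2, a regulator of microtubule dynamics, was 14.4-fold higher (4.62 to 72.2), from 3 junction reads to 47. Of these 12, the circles from Eln, Sftpc, Sftpb, Fbn1, Col5a1, Crip2, Hmcn1 and Col3a1 are repeat-end or few-pattern.

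Among lower circles, Hdgfl3 exons 2 to 5 (chromosome 7, 81893799 to 81905636) went from 78 to 5 junction reads between the pseudoglandular and alveolar libraries, 17.0-fold lower (6.99 to 53.8). Strn3 exons 2 to 16 was 11.2-fold lower (4.05 to 43.0), although the shorter Strn3 circle of exons 2 to 7 had 247 and 268 junction reads in these libraries. Rapgef6, a Rap exchange factor, was 9.09-fold lower (2.77 to 47.0), Ezh2 exons 2 to 15 7.79-fold (3.51 to 20.4), Bub1b exons 17 to 19 7.09-fold (2.98 to 20.5) and Zfp516 6.54-fold (2.73 to 18.997). Circles not listed in the alveolar library were at least 30.5-fold lower for Morc3, 15.3-fold for Gnas, 11.3-fold for Stip1 and 10.9-fold for Spopl, with those of Gnas and Stip1 few-pattern. Nlrp5-ps, a pseudogene, was at least 30.5-fold lower by exact coordinates, and 2.93-fold lower (223 to 83 reads) once 3 junctions within 5 bases of each other were merged. The split of 114 higher and 162 lower became 147 and 128 when libraries were scaled by the median of ratios and 162 and 98 when scaled by non-junction reads. Without repeat-end and few-pattern circRNAs it was 118 and 114.

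The gene lists placed these changes against random lists of matched abundance for the alveolar and pseudoglandular libraries. The type 2 list had a median log2 ratio of 7.64 (5.05 with unlisted hosts at their bound). The alveolar type 1 list, for the flat gas-exchange cells, stood at 4.40 (1.80 at the bound) over Radil, Lmo7 and Rtkn2, of which Radil, an effector of Rap, rose 3.48-fold (1.26 to 11.9). The other 2 were neither higher nor lower, and the list held 11 pseudoglandular and 56 alveolar reads. With 20 or more reads 1 type 1 host was measured, too few for a median. Endothelial hosts had a median of 2.08 (2.10 at the bound), with Pecam1, Prex2, Adgrf5 and Calcrl higher and Ldb2 lower. Extracellular matrix hosts had a median of 1.46 (also 1.46 at the bound), above all 10000 random lists, with 9 higher and 3 lower, the latter Fbn2, Col4a5 and Lama2. Smooth muscle and pericyte hosts had a median of 1.64 (1.61), where the cation channel gene Trpc6 rose 5.50-fold (3.32 to 9.63). Mesenchyme and fibroblast hosts had a median of 0.84 (0.90), with Macf1 13.6-fold higher (5.56 to 43.0), from 5 to 74 reads. Cell-cycle hosts had a median of -0.91 (-0.93) and Wnt hosts of -1.47 (-1.50). Each of these lists lay outside the central 95% of random lists, but with 20 or more reads the endothelial, smooth muscle, cell-cycle and Wnt medians came inside it, as did mesenchyme with non-junction scaling. With 20 or more reads the cell-cycle median itself stayed at -0.91, over 9 hosts, and the Wnt median at -1.47. In the matrix list 87.1% of alveolar junction reads came from repeat-end or few-pattern circRNAs, and without them the list held 0.733% of the pseudoglandular and 1.65% of the alveolar reads, with a median of 0.76 inside the central 95%. In the type 2 list 656 of 785 alveolar reads (83.6%) were of that kind, and without them its share went from 0.0240% to 0.526%. That left 2 measured hosts, too few for a median, and the Lamp3 circle of exons 2 to 5 alone gave 83 of the alveolar reads left.

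**Figure D1:**
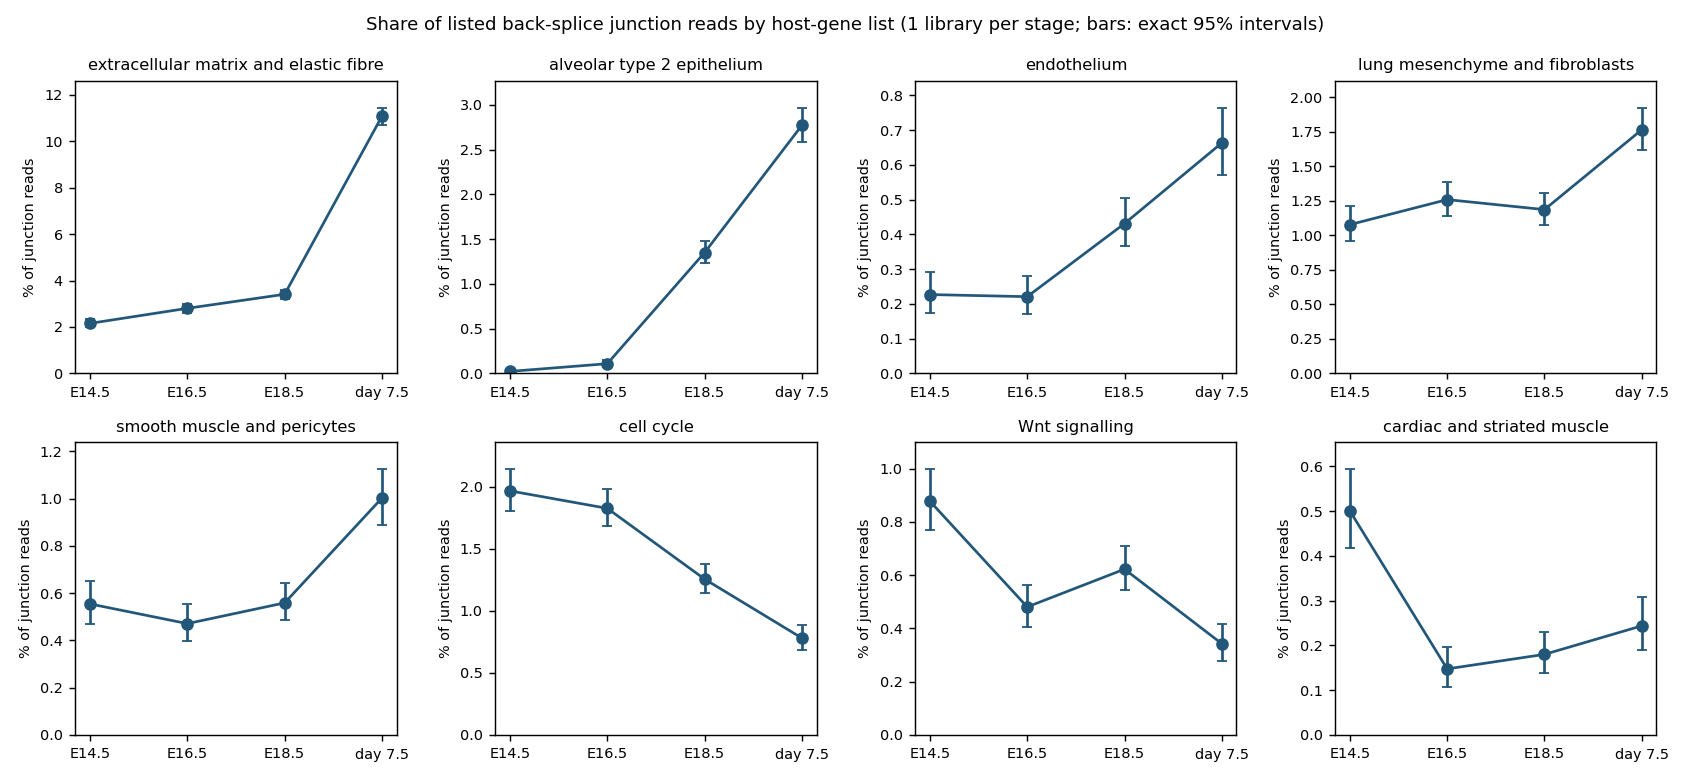
Share of junction reads (percent, linear axes that differ between panels) held by 8 of the gene lists, by deposited host, in each of the 4 libraries in order of stage, which are not spaced to time; points are shares, bars are exact 95% binomial intervals and lines join the same list. The matrix list goes from 2.16% in the pseudoglandular to 11.1% in the alveolar library and the cell-cycle list from 1.97% to 0.780%. Without repeat-end and few-pattern circRNAs, which are drawn here, the matrix shares in these libraries are 0.733% and 1.65%.

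**Figure D2:**
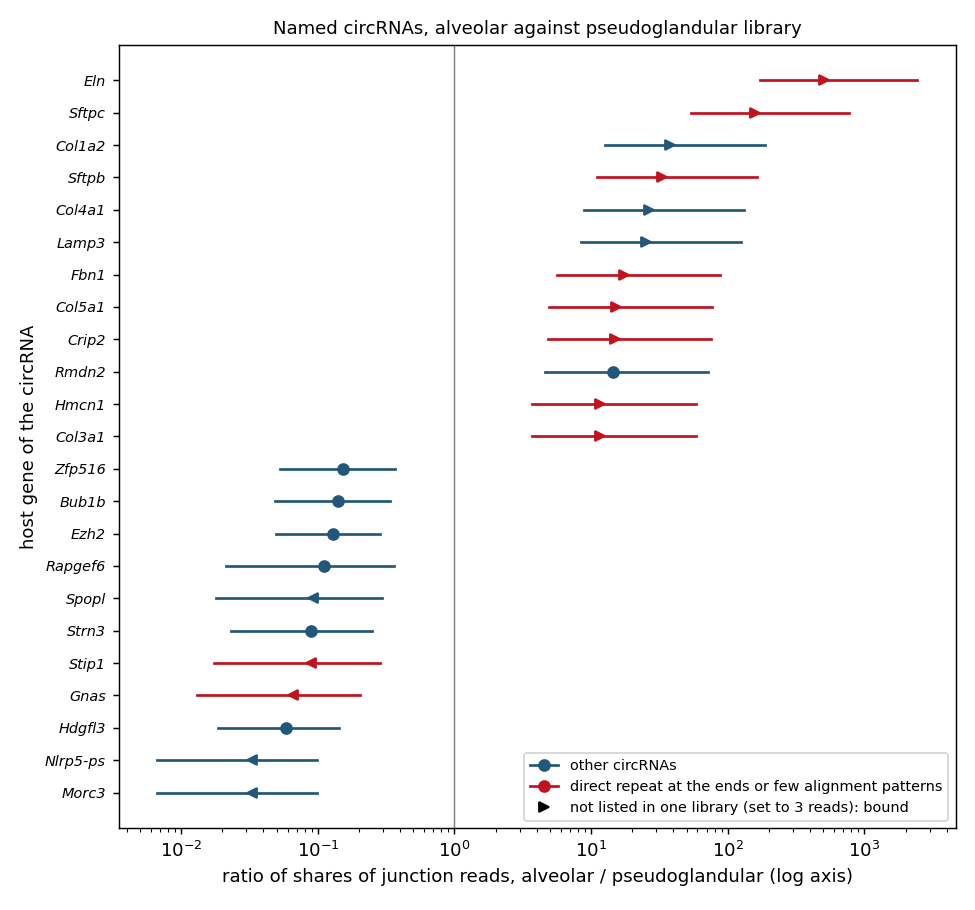
Ratio of shares of junction reads (log axis), alveolar against pseudoglandular, for the named circRNAs; points are ratios or, where the circRNA is listed in 1 of the 2 libraries, bounds, and bars are 95% counting intervals, in red for repeat-end or few-pattern circRNAs. Eln lies highest with at least 503-fold and Morc3 and Nlrp5-ps lowest with at least 30.5-fold lower by exact coordinates, though Nlrp5-ps was 2.93-fold lower with its neighbouring junctions merged.

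The canalicular library was compared with the pseudoglandular one for the earliest step. All 3 measured immune-cell hosts were higher: Mrc1, the macrophage mannose receptor, was 7.07-fold higher (1.68 to 63.1), the engulfment gene Elmo1 3.33-fold (1.07 to 13.7) and the receptor kinase gene Mertk at least 3.88-fold, and the list went from 0.0616% to 0.243% of junction reads. The cardiac and striated-muscle list went from 0.5003% to 0.147%, with 2 of its 4 measured hosts lower, Ttn (titin, the elastic filament of striated muscle) 6.77-fold (3.54 to 14.3) and the calcium-release channel gene Ryr2 at least 4.41-fold. Lists use deposited hosts, so an exon 2 circle of the cardiac-list gene Slc8a1 without one (165 and 79 reads) is left out; with hosts from the M21 annotation for such circles the cardiac list went from 1.14% to 0.4004%, with a median log2 ratio of -1.96. The immune list had a median log2 ratio of 2.54 (1.96 with unlisted hosts at their bound) and the cardiac list of -1.84 (-1.57), both outside the central 95% of random lists, with the cardiac list inside it at -0.98 with 20 or more reads. In that setting the immune list had 1 measured host, too few for a median. Of 1017 circRNAs compared, 83 were higher and 100 lower, against 8.42 and 12.7 from counting noise. The split turned over to 99 and 85 when scaled by non-junction reads, to 57 and 43 with 20 or more reads and to 59 and 56 for circRNAs listed in both libraries.

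Higher circles between the canalicular and pseudoglandular libraries were led by a Col4a1 circle of exons 24 to 27, at least 28.0-fold with 101 canalicular reads. Slc38a5, an amino-acid transporter gene, was at least 11.1-fold higher, Col6a1 9.43-fold, Gpbp1 8.32-fold, Ttc3 and Tln1 (talin) 7.77-fold each and Col6a2 6.94-fold, all lower bounds. Ascc2 went from 2 to 22 reads, 9.16-fold higher (2.25 to 80.3). Except for Ttc3 and Ascc2 these circles are repeat-end or few-pattern. Among lower circles, Ttn exons 123 to 127 was 6.52-fold lower (2.88 to 17.3), from 38 to 7 reads, and Sppl2a, a signal-peptide-peptidase-like protease gene, 12.6-fold lower (3.08 to 111). The Sppl2a junction lies in exon 15 of 15, with neither end at an annotated exon boundary. At least 16.8-fold lower was Gnas, with Stip1 at 12.4-fold, Spopl 12.01-fold, an intronic Ptprm circle 10.4-fold and Fbn2 9.61-fold. Of these, Gnas, Stip1 and Fbn2 are few-pattern. Nlrp5-ps was at least 33.6-fold lower by exact coordinates, while merging its neighbouring junctions gave 1.69-fold lower, under the 2-fold threshold.

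For the terminal sac against the canalicular library, the type 2 list went from 0.109% to 1.35% of junction reads and had a median log2 ratio of 2.24 (2.31 at the bound). Repeat-end or few-pattern circRNAs gave 76.2% of its terminal sac reads, and without them the share went from 0.113% to 0.340% and the median was 1.40, still outside the central 95% of random lists. Sftpc was at least 108-fold higher as a host, Lamp3 9.21-fold (4.01 to 26.0) and the phospholipid flippase gene Atp8a1 2.68-fold (1.28 to 6.12), and the transcription factor gene Etv5 was 3.47-fold lower (1.32 to 10.7). Cell-cycle hosts had a median of -0.56 (-0.57), with the helicase gene Hells 5.79-fold lower (1.64 to 31.2), the lamin gene Lmnb1 4.05-fold (1.80 to 10.3) and the kinetochore gene Knl1 2.42-fold (1.44 to 4.16). Both lists lay outside the central 95% of random lists, but cell cycle came inside it with 20 or more reads, without repeat-end and few-pattern circRNAs and, at percentile 4.12, with non-junction scaling. That scaling adds 0.63 to every log2 ratio of this comparison, which takes the cell-cycle median to 0.066.

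Of 1208 circRNAs compared between the terminal sac and canalicular libraries, 108 were higher and 135 lower (12.3 and 14.2 from counting noise), with 153 and 150 by host-gene sums and 299 and 46 when scaled by non-junction reads. Sftpc was at least 107-fold higher with 372 reads. A Col4a1 circle of exons 23 to 28 was at least 31.7-fold higher, Gm20425 25.6-fold, Spopl exons 2 to 7 17.8-fold, Os9 14.97-fold and Dvl2, a Wnt-pathway adaptor gene, 13.5-fold. Gbe1, the glycogen branching enzyme gene, was at least 10.9-fold higher by exact coordinates and 3.45-fold (2.25 to 5.48) with neighbouring junctions merged, from 27 to 108 reads. Nlrp5-ps was at least 34.0-fold higher by exact coordinates and 1.44-fold, under the threshold, when merged. Ascc2 was 12.7-fold lower (3.13 to 112). A Col4a1 circle of exons 34 to 35 was at least 16.2-fold lower, Slc38a5 15.4-fold, Col6a1 13.1-fold, the chromatin remodeller gene Chd4 11.97-fold, Gpbp1 11.6-fold, Tln1 10.8-fold and Col6a2 9.65-fold. Of all circles named for this step, those from Spopl, Gbe1, Nlrp5-ps and Ascc2 are neither repeat-end nor few-pattern.

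The alveolar library was set against the terminal sac one across birth. The matrix list went from 3.41% to 11.1% of junction reads, or from 0.698% to 1.65% without repeat-end and few-pattern circRNAs. Among all its circRNAs summed by host, Eln was 41.7-fold higher (31.5 to 56.2), Hmcn1, from 2 to 75 reads, 47.9-fold (12.8 to 402) and Frem1, a basement-membrane gene, 4.82-fold (2.26 to 11.4). Of the alveolar Eln reads, 1646 came from 1 repeat-end circle that the terminal sac library does not list. Of 8 endothelial hosts 3 rose, among them Pecam1 2.26-fold (1.31 to 4.01) and the angiopoietin receptor gene Tek 7.66-fold (1.70 to 70.4). In the type 2 list Sftpb was at least 45.9-fold higher and Lamp3 2.19-fold (1.60 to 3.03), whereas Atp8a1 was 2.02-fold lower (1.01 to 4.33). Without repeat-end and few-pattern circRNAs the type 2 share went from 0.340% to 0.526%, with 2 measured hosts left, too few for a median. Of 5 measured hosts of the epithelial progenitor and transcription factor list, 1 was lower and 4 were neither higher nor lower. Cebpa, a transcription factor gene, was at least 3.92-fold lower, and Foxp2 and Grhl2 went from 11 and 10 reads to unlisted. With 20 or more reads 2 hosts of this list were measured, too few for a median. Of 39 measured chromatin regulators 3 were higher, 4 lower and 32 neither. Among the lower, Phf21a was 2.73-fold lower (2.09 to 3.62) and Kmt2e 3.92-fold lower (1.31 to 15.8), and the higher were Baz2b, Chd4 and Arid1a. The Chd4 reads include 12 alveolar reads of a repeat-end and few-pattern circle that the terminal sac library does not list. Median log2 ratios were 1.54 (1.56 at the bound) for matrix, 0.90 (0.91) for endothelium, 1.13 (also 1.13) for type 2, -4.04 (-1.39) for progenitors and -0.57 (-0.65) for chromatin regulators, each outside the central 95% of random lists. Without repeat-end and few-pattern circRNAs the matrix median was 0.61, still outside it. The chromatin median came inside it in 5 of 6 other settings (percentiles 9.14, 5.94, 3.70, 3.14 and 2.53) and the endothelial median in 4 of 6 (96.9, 96.3, 97.49 and 97.3).

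Of 1123 circRNAs compared between the alveolar and terminal sac libraries, 118 were higher and 123 lower (15.6 and 10.6 from counting noise). The split was 141 and 92 with the median of ratios, 58 and 248 with non-junction scaling, 124 and 107 with totals that leave out the most abundant circRNA, and 120 and 88 without repeat-end and few-pattern circRNAs. The circle of Eln exons 17 to 22 was at least 700.2-fold higher. Col1a2 exons 8 to 10 was at least 52.7-fold higher, Sftpb 45.9-fold, Col5a1 21.3-fold, Crip2 20.8-fold, Hmcn1 and Col3a1 16.2-fold each and Slc34a2 11.5-fold. All of these but the Col1a2 circle, which had 22 alignment patterns for 124 reads, are repeat-end or few-pattern. The Col4a1 circle of exons 24 to 27 was at least 40.7-fold lower, Gm20425 23.2-fold, Spopl 16.2-fold, Os9 13.6-fold, Dvl2 12.3-fold and Morc3 11.5-fold, with those of Col4a1, Gm20425, Os9 and Dvl2 few-pattern. S100pbp, an S100P-binding protein gene, was 13.7-fold lower (3.52 to 118), from 35 to 2 reads. Nlrp5-ps was at least 30.8-fold lower by exact coordinates and 2.502-fold lower when merged.

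Several lists stayed inside the central 95% of random lists for the alveolar against the pseudoglandular library. Foetal growth hosts had a median log2 ratio of -1.18, the cardiac list -1.40 (outside it without repeat-end and few-pattern circRNAs and with M21 hosts where none is deposited), TGF-beta and BMP hosts -0.44, FGF, Hedgehog and Notch hosts 0.56, RNA-binding and splicing hosts -0.59, and hosts widely described for circRNAs -0.15. Lists with too few measured hosts are given as shares of junction reads from the pseudoglandular to the alveolar library. Ciliated and secretory airway hosts went from 0.0115% (interval 0.00238 to 0.0337) to 0.159% (0.116 to 0.212), erythroid hosts from 0.0924% (0.0592 to 0.137) to 0.134% (0.0949 to 0.184), and neuronal, neural crest and neuroendocrine hosts from 0.185% (0.136 to 0.245) to 0.0812% (0.0515 to 0.122). Immune-cell hosts went from 0.0616% (0.0352 to 0.09998) to 0.106% (0.0715 to 0.151) and epithelial progenitor hosts from 0.304% (0.241 to 0.379) to 0.289% (0.230 to 0.359). Mesothelial hosts as deposited had 6 junction reads in the pseudoglandular library, 8 in the canalicular and none listed later, and cartilage hosts 12 in the canalicular and 11 in the terminal sac library alone. With M21 hosts where none is deposited, mesothelial hosts had 6, 14, 0 and 4 junction reads in order of stage.

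The junction ratio, which sets junction reads against reads that run linearly across the same ends, compares circRNAs within a library without scaling between libraries. Over 895 circRNAs listed in all 4 libraries with 10 or more junction reads over them its median was 4.30% in the pseudoglandular library, 4.84% in the canalicular, 6.75% in the terminal sac and 5.04% in the alveolar. Ube2k, a ubiquitin-conjugating enzyme gene, followed the same order of libraries up to the terminal sac, with 28.2%, 34.5%, 54.6% and then 48.8%. By odds ratio, 219 circRNAs were higher and 29 lower in the terminal sac than in the canalicular library, and 36 higher and 197 lower in the alveolar than in the terminal sac. For the canalicular against the pseudoglandular library 99 were higher and 44 lower.

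For the alveolar against the pseudoglandular library 117 circRNAs had a higher junction ratio and 61 a lower one, of 798 compared, and 76 and 93 relative to the median circRNA, whose odds ratio was 1.18. The odds rose for Melk, a mitotic kinase gene, by 11.7-fold (3.55 to 38.5), Lbr (lamin B receptor) 9.41-fold (2.99 to 29.6), Rmdn2 8.75-fold (2.90 to 26.4), Pias1, a SUMO ligase gene, 8.54-fold (2.77 to 26.3), Marf1 7.96-fold (2.84 to 22.3) and the repair gene Rad52 4.57-fold (2.65 to 7.91). They were lower for Ldb2 by 8.62-fold (3.17 to 23.4), Strn3 exons 2 to 16 8.11-fold (3.05 to 21.6), Rapgef6 7.37-fold (2.38 to 22.8), Hdgfl3 5.81-fold (2.40 to 14.1) and Hipk3, a homeodomain-interacting kinase gene, 3.41-fold (2.27 to 5.13). The exon 2 circle of Hipk3 had 89, 95, 111 and 35 junction reads in order of stage. A change in odds can come from either kind of read. Melk had 4 and 7 junction reads and 536 and 76 non-junction reads in the pseudoglandular and alveolar libraries. For Ldb2 the junction reads were 13 and 5 and the non-junction reads 264 and 928.

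**Figure D3:**
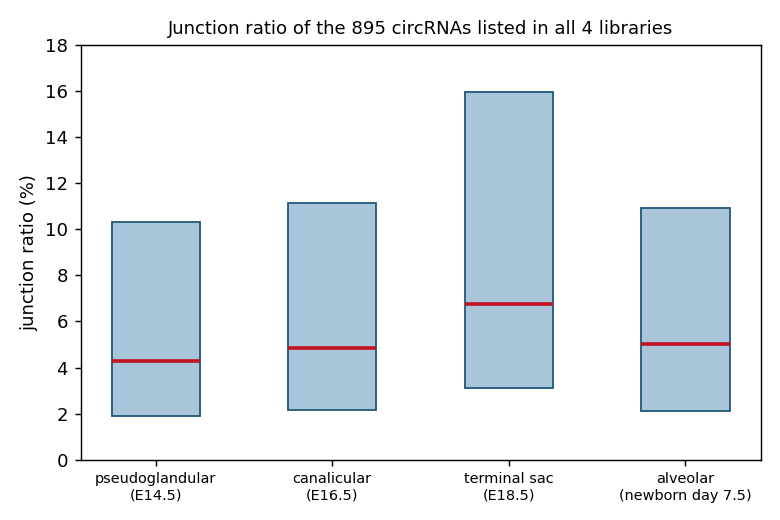
Junction ratio (percent, linear axis) of 895 circRNAs listed in all 4 libraries with 10 or more junction reads over them, by library in order of stage; boxes span the quartiles and lines are medians. The medians are 4.30%, 4.84%, 6.75% and 5.04%, with the terminal sac library highest.

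Across all 3 steps, 36 of 751 circRNAs with enough reads rose at every step, where flat profiles gave 35.3 on average and at most 57. The number that fell at every step was 56, against 35.2 on average and at most 52 in 1000 simulations. Flat profiles hold no shift shared by all circRNAs, whereas the median log2 ratio of the alveolar against the terminal sac library was -0.163. The number falling can therefore depend on scaling by totals, and no trend is read from it. The abundant circles of Col4a1 (277, 412, 583 and 722 junction reads) and Ube2k (134, 192, 253 and 200) were among those whose shares rose at every step. The Col4a1 circle is few-pattern. Since flat profiles gave about as many rising circRNAs, rising at every step does not by itself set a circRNA apart.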

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

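The test of an explanation for cardiac hosts in this part, and the use of hosts from M21, were chosen only after their results had been seen. The cardiac list and its median with hosts as deposited were planned. The circRNAs described next have no host gene in the deposited lists or lie on the mitochondrial chromosome, so the named comparisons do not use them. They were flagged because, with no control samples, their reads over the 4 libraries exceed 3. Many listed circRNAs pass that bar, 444 to 651 per library having 10 or more reads, so it does not set these apart. The circle at chromosome 17, 81647809 to 81649638, had 446 junction reads over the 4 libraries (165, 79, 73 and 129 in order of stage) and matches exon 2 of Slc8a1, a sodium-calcium exchanger gene, in the M21 annotation. It was 2.51-fold lower (1.91 to 3.32) in the canalicular than in the pseudoglandular library and 2.26-fold higher (1.68 to 3.05) in the alveolar than in the terminal sac. The circle at chromosome 9, 16374949 to 16378254, had 264 junction reads (18, 9, 28 and 209) and matches exon 2 of Fat3, an atypical cadherin gene. It was 10.6-fold higher (6.57 to 18.3) in the alveolar than in the pseudoglandular library. On the mitochondrial chromosome 11 junction reads were placed over the 4 libraries (2, 0, 6 and 3 in order of stage).

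Junction reads of cardiac and striated-muscle hosts were higher in the pseudoglandular than in the canalicular library, with a list median of -1.84 on the log2 scale from the earlier to the later library, at percentile 0.300 of random lists. Ttn went from 62 to 11 reads and Ryr2 from 11 to unlisted. Slc8a1 belongs to that list, and with hosts from M21 for circRNAs without a deposited one the median was -1.96 and the list held 1.14%, 0.4004%, 0.382% and 0.699% of junction reads in order of stage. Heart or great-vessel tissue taken with the youngest lungs may give this pattern, and so may the age of the tissue, which stays untested. The explanations cannot be told apart, because dissection and age changed together in 1 library per stage.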

How the results depend on the processing

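Of the alternatives in this part, merging of junctions within 5 bases, both ends at exon boundaries, removal of repeat-end and few-pattern circRNAs, non-junction scaling of lists and M21 hosts where none is deposited were chosen only after the data had been seen. The 72 named entries cover 46 distinct circRNAs, some in several comparisons, and of their folds 286 values under other scalings, the removal of the most abundant circRNA or merging kept direction and call, 2 (both Nlrp5-ps, when merged) fell under the threshold and 0 reversed. The named circRNAs are those with intervals farthest from 1, so the scalings could hardly undo a call and this count is little support. Of the 46 distinct circRNAs, 24 are repeat-end or few-pattern, whose removal is not among these values. Of 380 list medians, 353 stayed inside or outside the central 95% of random lists as before, 18 came inside it, 8 went outside it and 1 that had been outside changed sign. A further 21 changed sign while inside it in the reported setting, so the sign of a median inside that range can depend on the setting. Counts of calls stayed within 1.5 times of the reported ones under the median of ratios, host-gene sums, the exon type alone, both ends at exon boundaries, merging, totals without the most abundant circRNA, no read minimum and removal of repeat-end and few-pattern circRNAs. Thinning to the smallest total kept the numbers listed within the same bound.

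With 20 or more reads in the pair fewer circRNAs are compared, and the calls were 43 lower for the canalicular against the pseudoglandular library, 67 higher and 81 lower for the terminal sac against the canalicular, 67 higher for the alveolar against the terminal sac and 82 lower for the alveolar against the pseudoglandular. With circRNAs listed in both libraries, which leaves out those listed in 1, 56 were lower for the canalicular against the pseudoglandular and 75 higher for the alveolar against the pseudoglandular. Scaling by non-junction reads gave 299 higher and 46 lower for the terminal sac against the canalicular, 58 and 248 for the alveolar against the terminal sac, and 98 lower for the alveolar against the pseudoglandular; it shifts all ratios of a comparison alike.

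With 5 or more reads, a stricter minimum, the libraries listed 1215, 1485, 1717 and 1220 circRNAs in order of stage. The exon type then held 94.2%, 96.0%, 96.8% and 95.1% of reads, the intron type 2.46%, 1.52%, 1.67% and 1.99%, and the intergenic type 1.54% in the terminal sac library. With 10 or more reads, 99 circRNAs were listed in 1 library only. Median junction ratios were 5.13%, 5.91%, 8.55% and 6.16% with 20 or more reads over the 4 libraries, and 2.27%, 2.14%, 2.65% and 2.42% over all circRNAs of each library, and the cause was not tested; the terminal sac library was highest in each. Junction ratios of the alveolar against the pseudoglandular library gave 65 higher and 29 lower with 20 or more reads, where fewer are compared, and 76 and 93 relative to the median circRNA.

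List medians that came inside the central 95% with 20 or more reads were -0.52 for cell cycle (terminal sac against canalicular), -0.91 for cell cycle, 1.62 for endothelium, 0.54 for smooth muscle and -1.47 for Wnt (alveolar against pseudoglandular), 0.55 for endothelium and -0.46 for chromatin regulators (alveolar against terminal sac) and -0.98 for the cardiac list (canalicular against pseudoglandular). Others that came inside it were, for the alveolar against the terminal sac, endothelium at 1.08 with the median of ratios and chromatin regulators at -0.43 with 2 reads added and -0.996 with non-junction scaling, and mesenchyme at 1.14 with non-junction scaling for the alveolar against the pseudoglandular. Without repeat-end and few-pattern circRNAs, cell cycle at -0.33 (terminal sac against canalicular), endothelium at 1.02 and chromatin regulators at -0.40 (alveolar against terminal sac) and matrix at 0.76 (alveolar against pseudoglandular) came inside it. With non-junction scaling for the terminal sac against the canalicular, cell cycle moved to 0.066, at percentile 4.12 and inside it; the sign follows from the shift of 0.63 that this scaling gives every ratio of the comparison.

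Lists that went outside the central 95% were, for the alveolar against the terminal sac, mesenchyme at 0.66 with the median of ratios, 0.54 with 20 or more reads and 0.59 without repeat-end and few-pattern circRNAs, smooth muscle at 0.41 and immune cells at -2.19 with non-junction scaling, and Wnt at -0.99 with 2 reads added. The cardiac list at -1.36 did so for the alveolar against the pseudoglandular without repeat-end and few-pattern circRNAs. With M21 hosts where none is deposited, endothelium at 0.90 (percentile 97.3) and chromatin regulators at -0.57 (2.53) came inside it for the alveolar against the terminal sac and the cardiac list at -1.40 (1.77) went outside it for the alveolar against the pseudoglandular, each with its median as reported. For these list medians the cause was not tested. Depth limits what is listed at all, since 37.4% to 41.5% of each library's circRNAs had 2 reads.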

Other observations

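Of the tests in this part, those on the bulk and the remainder of the matrix reads, with its stricter bound, on elastin transcript and on a shared shift of the junction ratio by exonic length were chosen only after their results had been seen, as was the second ranking of named circRNAs that opens it. With junctions merged within 5 bases and without repeat-end and few-pattern circRNAs, the alveolar library was above the pseudoglandular for Pde5a, a cyclic-GMP phosphodiesterase gene, by 5.73-fold (3.91 to 8.62, from 32 to 180 reads), and for Trpc6 by 5.88-fold (3.54 to 10.3, from 18 to 104). Jup (plakoglobin) was 5.95-fold higher (3.28 to 11.7), the kinase gene Prkce 6.98-fold (3.14 to 18.3) and Ptprm, a receptor phosphatase gene, 9.16-fold (2.82 to 47.2). The Jup junction lies in exon 14 of 14, with neither end at an annotated exon boundary. The sodium-channel gene Scn7a was at least 10.2-fold higher and a Pecam1 circle of exons 8 to 13 at least 9.16-fold. The mismatch-repair gene Pms1 was 5.47-fold lower (2.42 to 14.5).

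Matrix-gene junction reads were high in the alveolar library, and 87.1% of them lay in repeat-end or few-pattern circRNAs, a share partly set by how those groups were defined. Outside the matrix list, 11 of the 37 circRNAs of 20 or more reads in the tenth with most non-junction reads were of that kind (29.7%, interval 15.9 to 47.0), against 10 of 328 of the rest (3.05%, 1.47 to 5.54). By-products of abundant linear transcripts may therefore account for such circles, and whether they account for the whole matrix difference cannot be told apart from a rise in matrix circRNAs: without them the list's share was 2.26 times higher in the alveolar than in the pseudoglandular library, but 211 of the 406 alveolar reads left came from Col1a2 exons 8 to 10 and Col4a1 exons 24 to 26, and the median of the hosts left was inside the central 95% of random lists against the pseudoglandular library (0.76, percentile 94.8) but just outside it against the terminal sac (0.61, percentile 97.6). A stricter bound (0.747% against 0.603%) decides nothing, because few patterns are sought where a circRNA has 10 or more reads, so the bound acts through the library in which it is abundant. More elastin transcript as the whole cause is argued against by the non-junction reads of the elastin circRNA listed in both the terminal sac and alveolar libraries. These went from 3680 to 5851, or 1.59-fold, while elastin junction reads rose 32.6-fold unscaled. The 1.59-fold rests on 1 circRNA. The 32.6-fold rests largely on another, a repeat-end circle with 1646 alveolar reads that the terminal sac library does not list, so it is not a rise across elastin circles. By-products in proportion to elastin transcript would meet the same values, with the same limits, so that explanation is not favoured for elastin either. The age of the tissue stays an open, untested explanation.

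The junction ratio was highest in the terminal sac library, where 71.2% of 1089 circRNAs had an odds ratio above 1 against the canalicular library. The planned count for a single shift shared by all circRNAs, 75 higher and 101 lower after division by the median odds ratio, decides nothing, because the division itself largely balances the counts. By exonic length the median odds ratio was 1.67 (1.53 to 1.76) for the 349 circRNAs of 506 bases or less and 1.28 (1.19 to 1.43) for the 349 of over 795 bases, which argues against one equal shift. A difference in fragment length between the libraries could give such a trend. Whether stage changes the ratio was not tested apart from it, and stays open.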
